A study of Mus musculus with 30 samples.

How the data were processed

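Total RNA of mouse hypothalamus had been extracted with Qiagen RNeasy columns, depleted of ribosomal RNA and made into libraries with the NEBNext Ultra II Directional kit. Per the submitters' processing notes, reads were aligned to mm10 (GRCm38) with HISAT2, counted per gene with featureCounts and compared with edgeR, without versions. The authors deposited 3 tables of raw gene counts, whole numbers that had not been normalised. There were 52286 genes in the fasting table, 55401 genes in the refeeding table and 22371 genes in the 1-month table. The authors also deposited edgeR tables of differential expression with a log2 fold change per gene computed by edgeR from the counts. In these tables the p-value comes from a likelihood ratio test, and a q-value and an adjusted p-value were derived from it by the authors. In all, 30 libraries in 9 groups were used, 2 further columns that match no library among the labels were not used, and no library was left out.

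Total counts per library were between 27.1 and 36.2 M in fed libraries, 27.7 and 32.4 M at 24 h, 31.5 and 43.4 M at 72 h, 32.5 and 34.8 M in the cold group, 28.5 and 33.1 M at 1 h, 26.1 and 34.1 M at 12 h, 46.9 and 64.3 M at 1 week, 10.4 and 13.5 M in 1-month controls and 9.35 and 13.8 M in 1-month refed libraries (M, 1e6 counts). A gene of 1 CPM was thus read from fewer counts in the 1-month libraries than in the others. Over genes with a mean of at least 20 counts, none of the 36 pairs of replicates differed by sampling noise alone, with chi-square per degree of freedom between 3.16 and 105. How far depth limited the precision of genes with fewer counts is left open by this. 

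Genes were matched by Ensembl identifier. Of 55401 identifiers 52269 had a symbol in the files, 3124 took theirs from GENCODE release M21, and 8 had none. How reads had been assigned to overlapping genes was checked. Among protein-coding genes with at least 100 counts in the 1-month table, 235 of 256 (91.8%) that lie inside a gene on the same strand and 422 of 459 (91.9%) that lie inside a gene on the opposite strand were at 0 in every fasting and refeeding library. Of 6474 genes without overlap 0 were. The fasting and refeeding tables thus appear to have been counted without strand and over whole gene spans, and the 1-month table not, though the options used are not stated. The share of a gene's span that other genes overlap is given where a named gene has much of it. Genes at 0 for this reason are not read as silent, and differences between the 1-month table and the others are not read as biology.

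Within each count table all groups were fitted together, and comparisons across tables were fitted on the groups of both tables. Genes were kept by filterByExpr of edgeR 4.0.16 (R 4.3.3), scaled by TMM and tested with robust quasi-likelihood F tests, with Benjamini-Hochberg adjustment in each comparison, a threshold of 0.05 and a prior count of 0.125. CPM values are on the TMM scale of the fit. The 10 comparisons, the genes to be named and the 45 gene lists were fixed before the data were examined, and 3 further lists, for liver, skeletal muscle and mitochondrial-like pseudogenes, were added after the data had been seen. Genes to be named were the called genes with the largest log2 fold changes in each direction, with a mean of at least 1 CPM over both groups and no overlap between the groups' libraries, which chance gives in 10% of genes for 3 against 3. Agrp, Npy, Pomc and Cartpt were named in every comparison, as were called members of the feeding peptide, receptor and neuroendocrine lists. From each other list came the called members with the smallest adjusted p and, where the list passed, a few uncalled ones, given as values. A part of these genes is printed. Sspn and Il31ra were chosen after their values were seen.

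Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01 and again with an estimated correlation, and with fry. Camera compares a list with all other genes. Fry's p-value asks whether a list's genes move on balance in a common direction and compares them with no other genes. Adjustment was over the lists of a comparison. Of 430 camera tests 126 passed at the preset correlation. Counts "adjusted over the list alone" apply the Benjamini-Hochberg step to a list's own genes.

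The fit was tested on simulated data, negative binomial counts with the means and dispersions of the libraries, in which 200 genes were changed in each comparison. The changed genes were taken from those above a minimum mean count, so recovery of genes with fewer counts was not measured. Of 3-fold changes edgeR recovered 88% for fed against 24 h, 79% from 24 h to 72 h, 87% for fed against 72 h, 79% for cold, 94% from 1 h to 12 h, 96% from 12 h to 1 week, 98% at 1 month, and 94%, 91% and 93% in the comparisons across tables. Of 1.5-fold changes it recovered 24%, 24%, 32%, 23%, 61%, 67%, 73%, 45%, 42% and 43% in the same order. False calls per comparison numbered between 5 and 12, and the sign was right in at least 98.5% of spiked genes. Each gene was drawn independently, so false calls from differences that many genes of a library share are not counted here.

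Replicate numbers were checked for pairing. Across groups of a table, the deviations of libraries of the same number had median correlations of 0.02, 0.04 and -0.04 in the fasting, refeeding and 1-month tables, against -0.01, -0.02 and 0.05 for libraries of other numbers, and groups were compared as unpaired. Alternatives tried were DESeq2 1.42.0, voom with quality weights, RLE size factors, no filter, a filter at a mean CPM of 1, the groups of a comparison fitted alone, 1 surrogate variable from sva 3.50.0, no mitochondrially encoded genes, a replicate block, and leaving out each library in turn. Mitochondrially encoded genes held no counts in any library, so leaving them out could not change a result. Alternatives added after the data had been seen were leaving out mitochondrial-like pseudogenes, leaving out the 3 libraries richest in their reads, removing the trend of fold change with gene span, and taking the fasting genes without fed library 2. Overlaps of genes were read from GENCODE spans with GenomicRanges 1.54.1.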

Results

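RNA from the hypothalamus of wild-type C57BL/6 mice was compared between 9 groups that were fed, fasted or refed. The first 4 groups were fed (n = 3), fasted for 24 h (n = 3), fasted for 72 h (n = 3) and fasted for 72 h in the cold at 18 C (n = 3). The others were refed after a 72 h fast for 1 h (n = 3), 12 h (n = 3), 1 week (n = 4) or 1 month (n = 4), with a fed control of the 1-month group (n = 4). Expression is given as TMM-normalised CPM, the library's share of counts on a common scale, with the SD between libraries, and changes as edgeR log2 fold changes (second group over first) ± SE. A gene was called when its Benjamini-Hochberg adjusted p from the edgeR quasi-likelihood test was below 0.05. The p-values measure the spread between samples, and whether each library came from a separate animal is not given in the sources used here. The counts came in 3 tables, for fasting, for refeeding up to 1 week and for the 1-month groups, and most comparisons below stay within a table.

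The first question was which genes differ after 24 h without food. Genes that respond to glucocorticoids were higher. Arrdc2, an arrestin-domain gene induced by steroid hormones (ENSMUSG00000002910, GRCm38 chromosome 8, 70835129 to 70839720), went from 8.98 ± 1.53 CPM in fed libraries (SD, n = 3) to 25.3 ± 1.57 CPM after 24 h (n = 3), a 2.82-fold rise (log2 fold change 1.49 ± 0.15, edgeR adjusted p = 0.00172). Fkbp5, a co-chaperone that restrains the glucocorticoid receptor (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), rose 1.99-fold from 36.4 ± 0.984 to 72.5 ± 4.47 CPM (0.99 ± 0.10, adjusted p = 0.00172). Cdkn1a, the cell cycle inhibitor p21 (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), rose 4.05-fold, from 7.52 ± 1.07 to 30.4 ± 3.85 CPM (2.02 ± 0.29, adjusted p = 0.0414). Other genes share 12.9% of the span of Fkbp5 and 10.7% of that of Cdkn1a. Pla2g3, a secreted phospholipase, and Itgad, an integrin alpha chain, rose by 1.84 ± 0.21 and 2.45 ± 0.34. These are 45% and 28.3% overlapped by other genes, and in the fasting and refeeding tables reads in shared stretches appear not to have been told apart by strand.

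The 2 genes called lower after 24 h were genes of the vessel wall. Myh11, the myosin heavy chain of smooth muscle, fell from 20.2 ± 4.45 to 7.76 ± 0.964 CPM (log2 fold change -1.38 ± 0.17, adjusted p = 0.0126), and Ptprb, an endothelial receptor phosphatase, fell by 0.67 ± 0.10 on the log2 scale (adjusted p = 0.0358). These 7 genes, 5 higher and 2 lower, were all that passed among 20408 tested, and 2118 had an unadjusted p below 0.05. In the list of glucocorticoid-responsive genes 3 of 25 tested were called, 13 when adjusted over the list alone, with a median log2 fold change of 0.45 (camera adjusted p = 5.09e-17 at a preset correlation, adjusted p = 0.0552 with an estimated correlation, fry adjusted p = 0.00591). Plin4, a lipid droplet coat gene in that list, stood at 28.6 ± 9.41 and 112 ± 4.90 CPM (1.97 ± 0.29, adjusted p = 0.0573) and was not called. Of the 13 pericyte and smooth muscle markers 1 was called lower, 7 when adjusted over the list alone (median -0.67, camera adjusted p = 1.63e-07, adjusted p = 0.0552 with an estimated correlation). The 14 endothelial markers held no called gene, 7 lower ones when adjusted over the list alone, and a median of -0.38 (camera adjusted p = 6.71e-07, adjusted p = 0.334 with an estimated correlation). Choroid plexus markers (median -0.92), blood cell markers (-0.85) and meningeal markers (-0.68) passed camera in the same direction, with adjusted p of 0.452, 0.452 and 0.484 with an estimated correlation. Summed choroid plexus markers were 78.3, 173 and 293 CPM in fed libraries 1 to 3 and 69.9, 88.4 and 70.8 CPM in the 24 h libraries, so fed library 1 lay within the range of the 24 h libraries.

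The peptides of the arcuate feeding circuit were not called at 24 h. Agrp, which drives feeding (ENSMUSG00000005705, chromosome 8, 105566698 to 105637393, 59.9% overlapped), stood at 4.89 ± 0.164 CPM in fed and 5.11 ± 0.194 CPM in fasted libraries (log2 fold change 0.06 ± 0.15, n = 3 each, edgeR adjusted p = 0.920). Npy, its partner peptide (ENSMUSG00000029819, chromosome 6, 49822710 to 49829507), had -0.05 ± 0.25 (adjusted p = 0.970). Pomc, the precursor of the satiety peptide alpha-MSH (ENSMUSG00000020660, chromosome 12, 3954951 to 3960642), had -0.50 ± 0.27 (adjusted p = 0.562), and Cartpt, a satiety peptide gene (ENSMUSG00000021647, chromosome 13, 99898489 to 99901091), -0.10 ± 0.36 (adjusted p = 0.950). Reads over the whole span of Agrp appear to have been counted in these libraries. Whether reads from outside its transcript hid a change of Agrp, here or in the later comparisons of fasting libraries, was not tested. The count of 7 called genes became 4 without fed library 1, 4 without 24 h library 1, 3 without 24 h library 3 and 56 without 24 h library 2, and DESeq2 called 240, voom with quality weights 3952 and edgeR with 1 surrogate variable 23. Fkbp5, Arrdc2 and Pla2g3 kept their calls without any single library, while Cdkn1a, Itgad, Myh11 and Ptprb each lost theirs without at least 1. With the 2 groups fitted alone Pla2g3, Myh11 and Ptprb lost their calls. Without the 3 libraries richest in mitochondrial-like reads Cdkn1a, Itgad and Ptprb lost theirs. Of the 7 calls 4, 3 and 2 were lost without fed libraries 1, 2 and 3, and 3, 1 and 4 without 24 h libraries 1, 2 and 3.

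**Figure D1:**
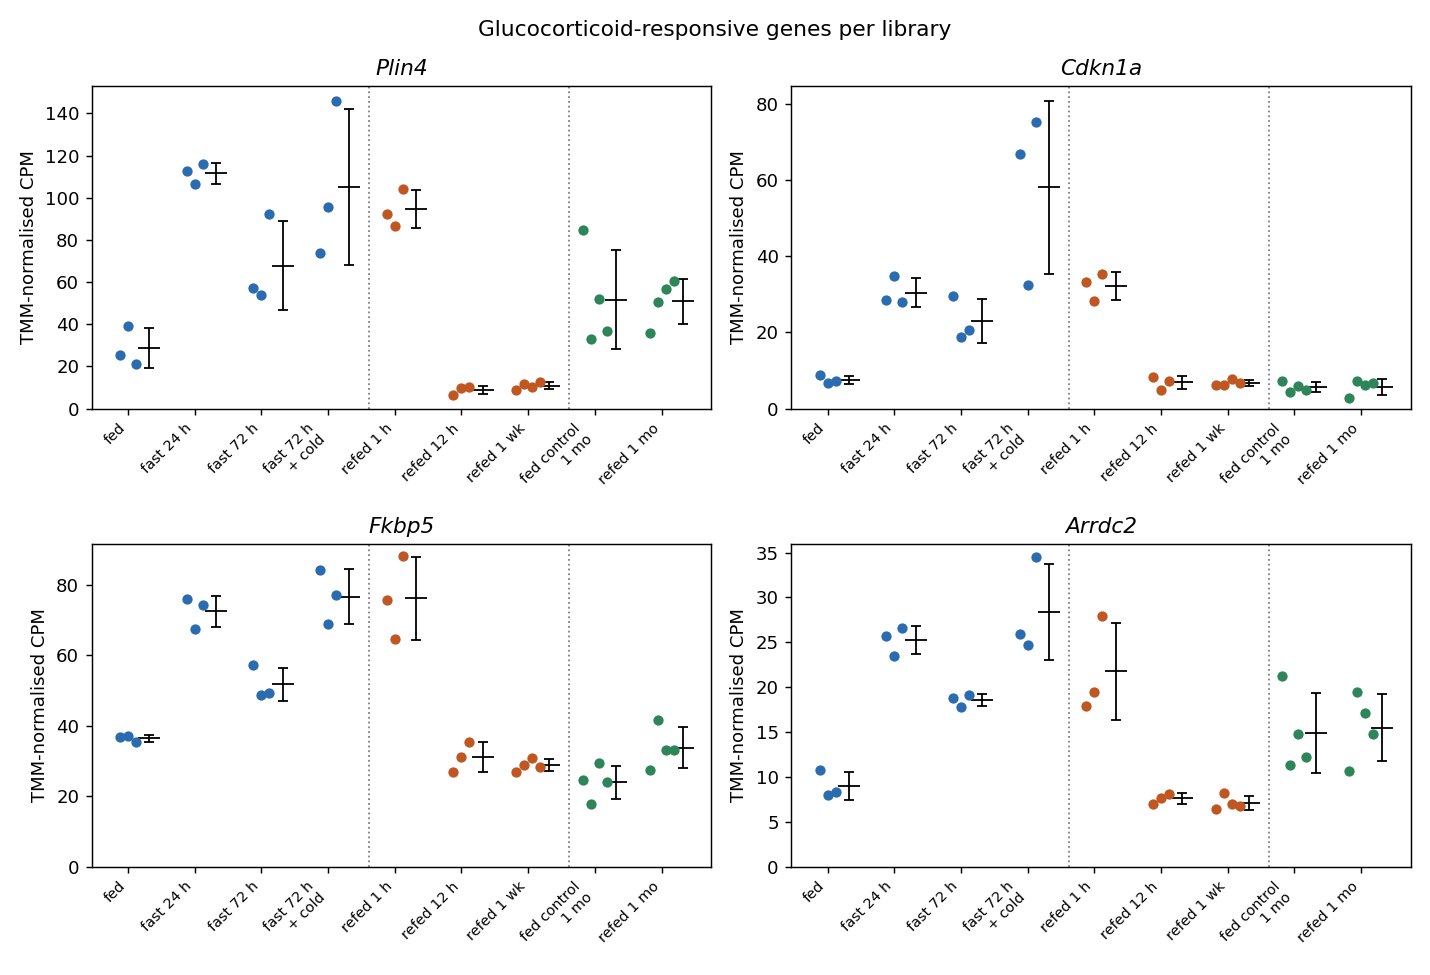
TMM-normalised CPM of Plin4, Cdkn1a, Fkbp5 and Arrdc2 in each library, with a dot per library, bars for mean ± SD per group, and colours and dotted lines that part the 3 count tables. Plin4 stood at 94.5 ± 8.97 CPM after 1 h of refeeding and at 8.85 ± 1.92 CPM after 12 h.

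The next comparison asked what changes between 24 h and 72 h of fasting. Genes induced by neuronal activity were lower at 72 h. Fos, an immediate early transcription factor (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273), fell from 12.9 ± 4.34 to 3.13 ± 0.658 CPM (log2 fold change -2.03 ± 0.28, n = 3 each, adjusted p = 0.00800). Junb fell by 1.82 ± 0.23, Arc by 1.57 ± 0.21, Nr4a1 by 1.46 ± 0.20 and Egr3 by 2.91 ± 0.43 on the log2 scale. Genes of striatal projection neurons fell too. The dopamine receptor gene Drd1 (ENSMUSG00000021478, chromosome 13, 54051183 to 54055705) fell from 41.3 ± 13.8 to 6.01 ± 4.21 CPM (-2.78 ± 0.58, adjusted p = 0.0461). The adenosine receptor gene Adora2a (-3.52 ± 0.75) and the enkephalin gene Penk (-1.87 ± 0.35) moved with it. Slc2a1, the glucose transporter of the blood-brain barrier (17.1% overlapped), fell by 0.63 ± 0.09, and Pdk4, which holds pyruvate back from oxidation, by 1.01 ± 0.17. Fkbp5 fell by 0.48 ± 0.10 from its 24 h level (adjusted p = 0.0326), and Npy1r, a receptor for neuropeptide Y, by 0.72 ± 0.16 (adjusted p = 0.0430).

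Of the 333 genes called between 24 h and 72 h, 116 were higher and 217 lower. Of 12 striatal neuron markers 8 were lower, 11 when adjusted over the list alone (median -1.70, camera adjusted p = 2.31e-12, adjusted p = 0.263 with an estimated correlation, fry adjusted p = 0.00561). Of 30 immediate early genes 14 were lower, 24 when adjusted over the list alone (median -0.90, camera adjusted p = 3.48e-16, adjusted p = 0.311 with an estimated correlation, fry adjusted p = 0.0126). Summed CPM of the striatal markers was 884, 956 and 889 in the 24 h libraries and 464, 403 and 441 in the 72 h libraries. Nuclear oxidative phosphorylation genes (median -0.49) and cytosolic ribosomal protein genes (-0.46) passed camera as lower, with 1 of 32 and 0 of 37 genes called, 20 and 29 when adjusted over the list alone, and an adjusted p of 0.594 with an estimated correlation for each. Opalin, a gene of mature oligodendrocytes, rose 2.12-fold from 12.3 ± 0.306 to 26.0 ± 3.43 CPM (1.08 ± 0.25, adjusted p = 0.0478). Among the genes called higher with the largest fold changes were Vmn2r56 from 0.206 ± 0.126 to 2.13 ± 0.836 CPM (3.30 ± 0.52) and Atp1a4 from 0.678 ± 0.371 to 3.98 ± 1.28 CPM (2.55 ± 0.54). Longer genes rose more across all genes (Spearman rho of fold change with gene span 0.37, over genes, which are not independent replicates). Agrp (0.08 ± 0.14), Npy (-0.14 ± 0.25), Pomc (-0.04 ± 0.27) and Cartpt (0.07 ± 0.36) were not called. The 333 calls became 0 without 72 h library 3, 1 without 72 h library 2 and 77 without 72 h library 1. They became 71 without 24 h library 2 and 120 without 24 h library 3. Leaving out a library also leaves fewer degrees of freedom, so these losses do not show that a single library made the calls. All 31 called genes chosen for the text lost their calls without 72 h library 2 or 3, 19 without 72 h library 1, and 11, 18 and 13 without 24 h libraries 1, 2 and 3. EdgeR with 1 surrogate variable called 0 genes (1540 at an unadjusted p below 0.05) and all 31 lost their calls, while DESeq2 called 1776 and voom with quality weights 2909.

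The comparison of fed with 72 h fasted libraries asked for the whole change of a long fast. Of 25 glucocorticoid-responsive genes 5 were higher than in fed libraries, 5 higher and 1 lower when adjusted over the list alone, and the list did not pass (median 0.08, camera adjusted p = 0.248). Cdkn1a was 3.06-fold higher (log2 fold change 1.61 ± 0.28, n = 3 each, adjusted p = 0.00963), Arrdc2 2.07-fold (1.05 ± 0.15, adjusted p = 0.00500) and Fkbp5 1.42-fold (0.51 ± 0.10, adjusted p = 0.0113). Hif3a, an inhibitor of the hypoxia response, was 1.79-fold higher, and Cirbp, a cold-inducible RNA-binding protein gene, was 1.53-fold higher (0.61 ± 0.09, adjusted p = 0.00651). Clock genes moved both ways, with Arntl at 0.47 ± 0.13, Rora at 0.52 ± 0.15 and Clock at -0.27 ± 0.08. Activity-induced genes were lower, with Fos at 13.3 ± 4.10 and 3.13 ± 0.658 CPM (-2.08 ± 0.28, adjusted p = 0.00500), Arc at -1.78 ± 0.21 and Homer1 at -0.99 ± 0.14. Vascular genes were lower, with Myh11 at -1.90 ± 0.18 (adjusted p = 0.00157), Acta2 at -1.81 ± 0.26, the pericyte gene Rgs5 at -1.08 ± 0.16 and the endothelial genes Flt1 at -0.65 ± 0.11 and Abcb1a at -0.57 ± 0.09. Chaperone genes were lower, with Pdia4 at -0.90 ± 0.12, Chordc1 at -0.79 ± 0.10 and Hsph1 at -0.77 ± 0.16.

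Receptors of feeding peptides were among the genes lower after 72 h. Npy1r fell by 0.61 ± 0.16, Npy2r by 0.68 ± 0.18 and Npy5r by 0.68 ± 0.17 on the log2 scale, and Mchr1, the receptor of melanin-concentrating hormone, by 0.93 ± 0.20 (adjusted p = 0.0151). The list of feeding receptors did not pass camera (adjusted p = 0.381), with 5 of 20 lower, 1 higher and 6 lower when adjusted over the list alone, a median of 0.03 and a mean of -0.08. Of the peptide genes, Ghrl, which encodes ghrelin and is 18.6% overlapped, rose from 5.38 ± 0.554 to 8.54 ± 0.985 CPM (0.67 ± 0.17, adjusted p = 0.0283). Pdyn, the dynorphin gene, fell by 0.99 ± 0.27 (adjusted p = 0.0351). Agrp (0.14 ± 0.15), Npy (-0.19 ± 0.25), Pomc (-0.54 ± 0.27) and Cartpt (-0.03 ± 0.36) were not called, with adjusted p of 0.519, 0.622, 0.180 and 0.953. Npy1r, Npy2r, Npy5r, Mchr1, Ghrl and Pdyn each lost their call without at least 1 single library and with 1 surrogate variable. In fed libraries 1 to 3 Mchr1 stood at 12.5, 15.1 and 8.63 CPM and Pdyn at 26.7, 40.9 and 20.7 CPM. Summed striatal markers were 679, 931 and 580 CPM there and 464, 403 and 441 CPM in the 72 h libraries. Npy1r followed that order too, while Npy2r (19.4, 22.6 and 24.4 CPM) and Npy5r (5.61, 5.42 and 4.95 CPM) did not. Whether striatal tissue took part in these falls was not tested.

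Of 3072 genes called between fed and 72 h fasted libraries, 1485 were higher and 1587 lower, 911 by more than 2-fold, and 20 gene lists passed camera, all as lower. Immediate early genes had 20 of 30 lower and 1 higher, 25 lower and 1 higher when adjusted over the list alone (median -0.94, camera adjusted p = 1.28e-12, adjusted p = 0.460 with an estimated correlation). Endoplasmic reticulum chaperones had 13 of 20 lower, 16 when adjusted over the list alone (median -0.47), and heat shock chaperones 11 of 19, 18 when adjusted over the list alone (median -0.59), each with an adjusted p of 0.460 with an estimated correlation. Endothelial markers had 10 of 14 lower, 11 when adjusted over the list alone (median -0.64, camera adjusted p = 1.79e-07, adjusted p = 0.450 with an estimated correlation, fry adjusted p = 0.00256). Blood cell markers had 7 of 10 lower by either adjustment (median -1.93, adjusted p = 0.460 with an estimated correlation), and Hbb-bs, a haemoglobin gene, fell by 2.71 ± 0.40. Striatal markers had 7 of 12 lower, 10 when adjusted over the list alone (median -1.31, adjusted p = 0.460 with an estimated correlation). Cytosolic ribosomal protein genes had 12 of 37 lower, 31 when adjusted over the list alone (median -0.50, adjusted p = 0.460 with an estimated correlation). Over all genes the fold change rose with gene span (Spearman rho 0.28). Pseudogenes that resemble mitochondrial genes took 5.56%, 5.44% and 3.86% of counts in the fed libraries and between 2.56% and 3.01% in the 72 h libraries, and 5 of 7 were called lower.

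Liver and skeletal muscle transcripts fell by much more in the fed against 72 h comparison. Alb, the serum albumin gene (ENSMUSG00000029368, chromosome 5, 90460897 to 90476602), had 233 ± 327 CPM in fed and 0.333 ± 0.172 CPM in 72 h libraries (log2 fold change -9.50 ± 2.15, adjusted p = 0.0263), and Myh4, a myosin gene of fast muscle, 260 ± 443 and 0.356 ± 0.0535 CPM (-9.51 ± 2.45, adjusted p = 0.0356). The SD in fed libraries exceeded the mean because fed library 2 held 1353 CPM of liver list transcripts and 1705 CPM of muscle list transcripts, against 9.44 and 10.6 CPM in fed library 1 and 211 and 29.9 CPM in fed library 3. The 72 h libraries held between 7.0 and 9.42 CPM of liver and between 8.26 and 12.0 CPM of muscle transcripts, and the 24 h libraries held 72.0, 239 and 91.2 CPM of liver and between 12.3 and 15.7 CPM of muscle transcripts. The count of 3072 called genes became 830 without fed library 1, 456 without fed library 2, 5446 without fed library 3, and 1056, 712 and 434 without 72 h libraries 1, 2 and 3. Of the 51 called genes chosen for the text, 24 kept their calls without any single library, among them Fos, Arc, Homer1, Fkbp5, Arrdc2, Cdkn1a, Hif3a, Cirbp, Myh11, Acta2, Flt1, Abcb1a, Rgs5, Pdia4, Chordc1 and Hbb-bs. The others lost 13 and 19 calls without fed libraries 1 and 2, none without fed library 3, and 17, 23 and 27 without 72 h libraries 1, 2 and 3. The fit with 1 surrogate variable, however, called 2 genes, and 50 of the 51 lost their calls, all but Myh11, while DESeq2 called 4707 and voom with quality weights 7554.

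**Figure D2:**
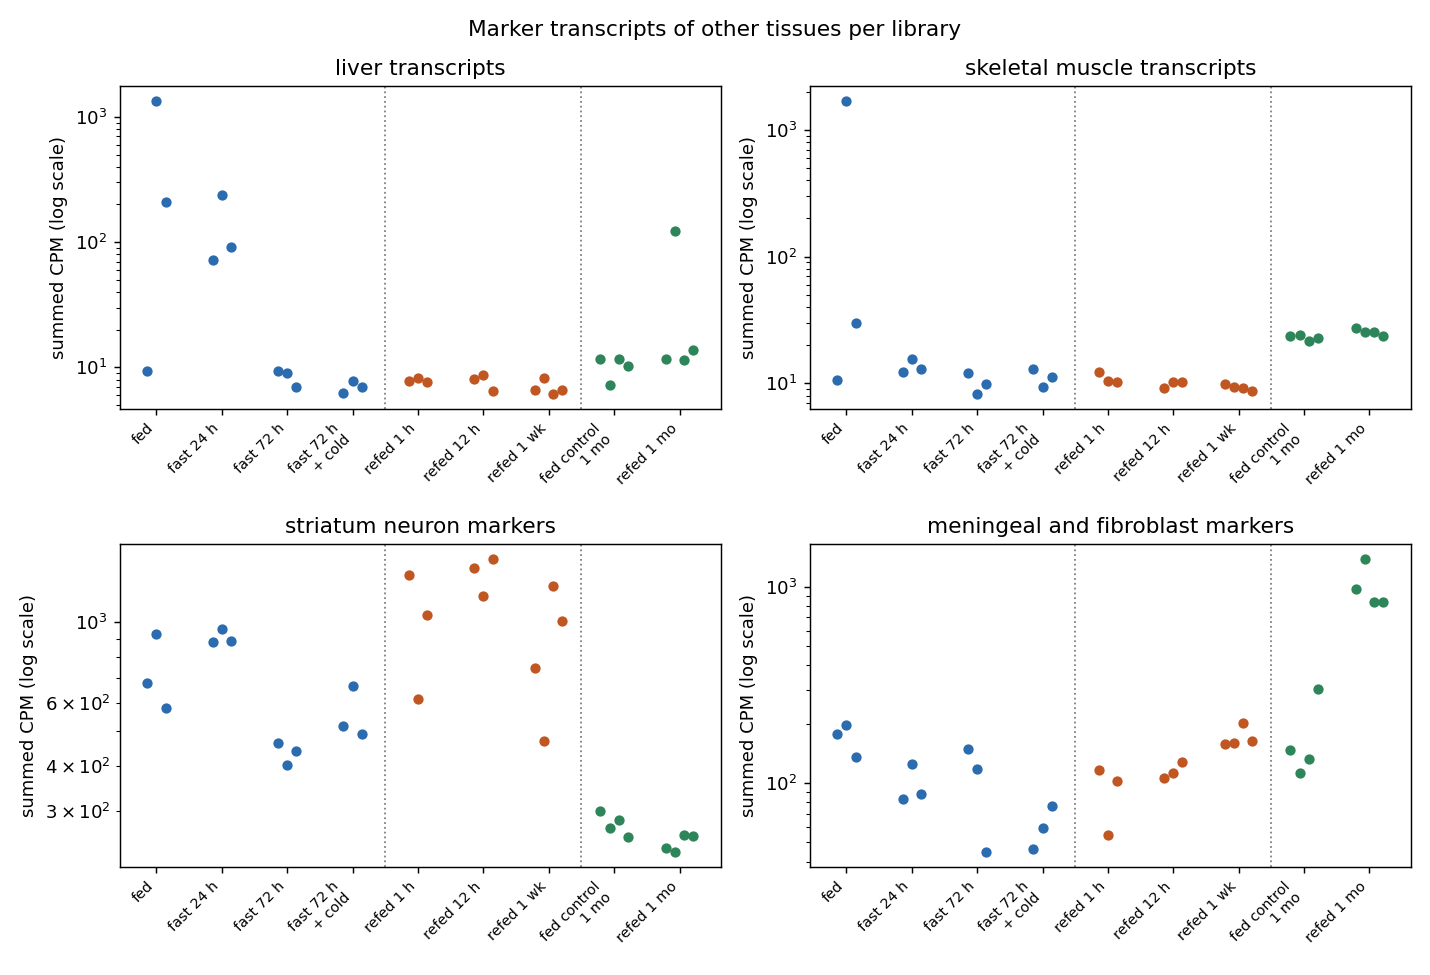
Summed CPM on a log axis of the liver, skeletal muscle, striatal and meningeal gene lists in each library, with a dot per library and groups along the horizontal axis. Fed library 2 stood at 1353 CPM for the liver list and 1705 CPM for the muscle list, and the refed 1-month libraries stood at or above 839 CPM for the meningeal list.

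Cold exposure during the 72 h fast was compared with the 72 h fast alone to ask what a cold challenge adds. No gene was called by edgeR among 20408 tested, 1296 had an unadjusted p below 0.05, and DESeq2 called 57 and voom with quality weights 28. Glucocorticoid-responsive genes moved as a group, with a median log2 fold change of 0.57 over 25 genes (n = 3 per group, camera adjusted p = 9.05e-28, fry adjusted p = 0.00877). This was the only one of the 126 camera calls of the 10 comparisons that held with an estimated correlation (adjusted p = 0.0242), and 17 of the 25 genes were higher when adjusted over the list alone. Fkbp5 stood at 51.8 ± 4.72 CPM without and 76.7 ± 7.74 CPM with cold (0.57 ± 0.10, adjusted p = 0.203). Ddit4, a stress-induced inhibitor of mTOR signalling (ENSMUSG00000020108, chromosome 10, 59949669 to 59951834), stood at 25.9 ± 2.67 and 52.8 ± 10.7 CPM (1.02 ± 0.16, adjusted p = 0.203). Cholesterol synthesis genes had a median of -0.24 over 24 genes, of which 4 were lower when adjusted over the list alone (camera adjusted p = 9.99e-10, adjusted p = 0.814 with an estimated correlation). Markers of the arcuate and ventromedial nuclei had a median of -0.57 over 12 genes, of which 3 were lower when adjusted over the list alone (camera adjusted p = 2.49e-05, adjusted p = 0.814 with an estimated correlation). Other region and tissue lists passed camera beside them without a called gene, thalamic markers as higher (median 0.44, camera adjusted p = 0.000926) and meningeal (-0.68, 0.00224) and paraventricular and supraoptic markers (-0.26, 0.0316) as lower, each with an adjusted p of 0.814 with an estimated correlation. Summed meningeal markers were 149, 118 and 44.7 CPM without and 46.5, 59.5 and 76.3 CPM with cold. In all, 11 lists passed camera, 6 as higher and 5 as lower. Those of immediate early, glycolysis, oxidative phosphorylation, ribosomal protein and interferon-stimulated genes were also among them. Fos stood at 3.13 ± 0.658 CPM without and 6.90 ± 1.04 CPM with cold (1.14 ± 0.27, adjusted p = 0.450). Agrp stood at 5.39 ± 0.668 and 3.59 ± 0.0159 CPM (-0.59 ± 0.15, adjusted p = 0.469) and Pomc at 4.23 ± 1.20 and 2.31 ± 0.727 CPM (-0.87 ± 0.28, adjusted p = 0.598). Npy (0.01 ± 0.25) and Cartpt (0.14 ± 0.35) were also not called. Without single libraries edgeR called 5 genes (without cold library 3), 2 (without 72 h library 3) or 1 (without cold library 2). With simulated changes at this depth, in genes above a minimum mean count, it recovered 79% of 3-fold and 23% of 1.5-fold changes.

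The hypothalamus 1 h and 12 h into refeeding was compared to ask how fast the fasting pattern ends once food returns. Plin4 (ENSMUSG00000002831, chromosome 17, 56100591 to 56109803) dropped 10.6-fold, from 94.5 ± 8.97 to 8.85 ± 1.92 CPM (log2 fold change -3.41 ± 0.16, n = 3 each, adjusted p = 9.30e-07). Cdkn1a fell 4.70-fold, from 32.2 ± 3.66 to 6.87 ± 1.69 CPM (adjusted p = 3.82e-06). Mt1, a zinc-binding metallothionein induced by glucocorticoids (ENSMUSG00000031765, chromosome 8, 94179082 to 94180327), fell 3.02-fold, from 158 ± 12.6 to 52.3 ± 3.6 CPM (adjusted p = 8.11e-08). Among the fasting libraries Mt1 stood at 179 ± 24.2 CPM in fed, 223 ± 51.35 CPM at 24 h and 160 ± 18.5 CPM at 72 h. Its fall is thus not read as the end of a rise with the 72 h fast. Itgad fell by 2.70 ± 0.15 on the log2 scale, Hif3a by 2.06 ± 0.33 and the transcription factor Klf15 by 0.86 ± 0.07. Of 24 glucocorticoid-responsive genes 19 were lower, 21 when adjusted over the list alone (median -0.92, camera adjusted p = 1.23e-22, adjusted p = 0.167 with an estimated correlation, fry adjusted p = 0.000967). The clock repressors Per1, which glucocorticoids also induce (-0.97 ± 0.10, adjusted p = 8.61e-05), and Per2 (-0.53 ± 0.06, adjusted p = 0.000148) were lower. Of 18 clock genes 8 were lower, 9 lower and 1 higher when adjusted over the list alone (median -0.29, camera adjusted p = 0.000537, adjusted p = 0.167 with an estimated correlation). The time of day of collection is not given in the sources used here. The cold-inducible RNA-binding genes Rbm3 and Cirbp fell by 1.49 ± 0.13 and 1.18 ± 0.13.

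Some genes of fuel use were also lower at 12 h. Pdk4 fell from 12.9 ± 2.19 to 5.90 ± 1.21 CPM (log2 fold change -1.12 ± 0.17, adjusted p = 0.00128). Slc2a4, the insulin-regulated glucose transporter, fell from 4.63 ± 0.416 to 1.5 ± 0.505 CPM (-1.64 ± 0.28), and Irs2, an insulin receptor substrate repressed by insulin, fell by 0.41 ± 0.07. Of 28 genes of fatty acid oxidation and ketone use 6 were lower and 2 higher, 7 and 3 when adjusted over the list alone, and the list did not pass (median -0.10, camera adjusted p = 0.0726). Of 22 genes of glycolysis and glucose uptake 4 were lower, 5 lower and 1 higher when adjusted over the list alone (median -0.13, camera adjusted p = 0.00187, adjusted p = 0.791 with an estimated correlation). Of 20 genes raised by FoxO factors when insulin is low, 7 were lower, 8 when adjusted over the list alone (median -0.24, camera adjusted p = 0.000352, adjusted p = 0.329 with an estimated correlation). Of the 22 amino acid response genes under ATF4 7 were lower and 1 higher, 9 lower and 1 higher when adjusted over the list alone (median -0.14, adjusted p = 0.674 with an estimated correlation), with Atf4 itself at -0.49 ± 0.08. Immediate early genes were lower at 12 h, with Fos from 31.1 ± 2.43 to 19.6 ± 2.74 CPM (-0.66 ± 0.11, adjusted p = 0.00154) and Junb at -0.92 ± 0.16. Of 30 such genes 13 were lower, 19 when adjusted over the list alone (median -0.57, camera adjusted p = 2.11e-10, adjusted p = 0.329 with an estimated correlation).

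The feeding peptides moved apart between 1 h and 12 h of refeeding. Npy fell from 30.1 ± 2.32 to 21.7 ± 2.64 CPM (log2 fold change -0.47 ± 0.11, n = 3 each, adjusted p = 0.0126). Agrp (59.9% overlapped) rose from 5.50 ± 0.858 to 7.72 ± 0.410 CPM (0.49 ± 0.12, adjusted p = 0.0178). Whether reads from outside the Agrp transcript took part in that rise was not tested. Cartpt rose from 20.1 ± 0.368 to 30.8 ± 0.653 CPM (0.62 ± 0.08, adjusted p = 0.000482). Ghsr, the ghrelin receptor gene, fell by 0.71 ± 0.18 and Ghrl by 0.49 ± 0.12. Vgf, a precursor of energy-balance peptides, fell by 0.31 ± 0.07, and the adiponectin receptor gene Adipor2 by 0.71 ± 0.09. Pomc was not called (1.31 ± 1.06, adjusted p = 0.473), and its level at 12 h was 20.9 ± 26.3 CPM.

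Immune and glial genes rose between 1 h and 12 h of refeeding. Of 19 interferon-stimulated genes 13 were higher, 15 when adjusted over the list alone (median 0.80, camera adjusted p = 3.48e-08, adjusted p = 0.421 with an estimated correlation, fry adjusted p = 0.0149). Ifitm3, an antiviral membrane protein gene (ENSMUSG00000025492, chromosome 7, 141009586 to 141010770), went from 2.94 ± 0.434 to 6.07 ± 0.668 CPM (log2 fold change 1.05 ± 0.17, adjusted p = 0.00153), and Gbp2 from 1.18 ± 0.327 to 2.75 ± 0.324 CPM (1.21 ± 0.23). Of 14 microglia markers 5 were higher, 9 when adjusted over the list alone (median 0.28, camera adjusted p = 0.000189, adjusted p = 0.675 with an estimated correlation), with Tmem119 at 0.60 ± 0.12 and Siglech at 0.66 ± 0.13. Oligodendrocyte genes Ugt8a (0.97 ± 0.09) and Opalin (0.84 ± 0.11) were higher, and so were Fabp7, a fatty acid binding protein gene of glia (1.49 ± 0.19), and the chaperone gene Hsph1 (0.54 ± 0.08). In all, 2834 genes were called, 1411 higher and 1423 lower, 305 by more than 2-fold, and over all genes the fold change rose with gene span (Spearman rho 0.27). The count became 1716 without 1 h library 1, 1417 without 1 h library 2, 1632 without 12 h library 2 and 1314 without 12 h library 3. Of 53 called genes chosen for the text 47 kept their calls without any single library. Rpl37, Npy, Agrp, Ghsr, Ghrl and Prkcd did not, as 5 calls were lost without 1 h library 2, 5 without 12 h library 3, 2 without 1 h library 1 and 2 without 12 h library 2.

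**Figure D3:**
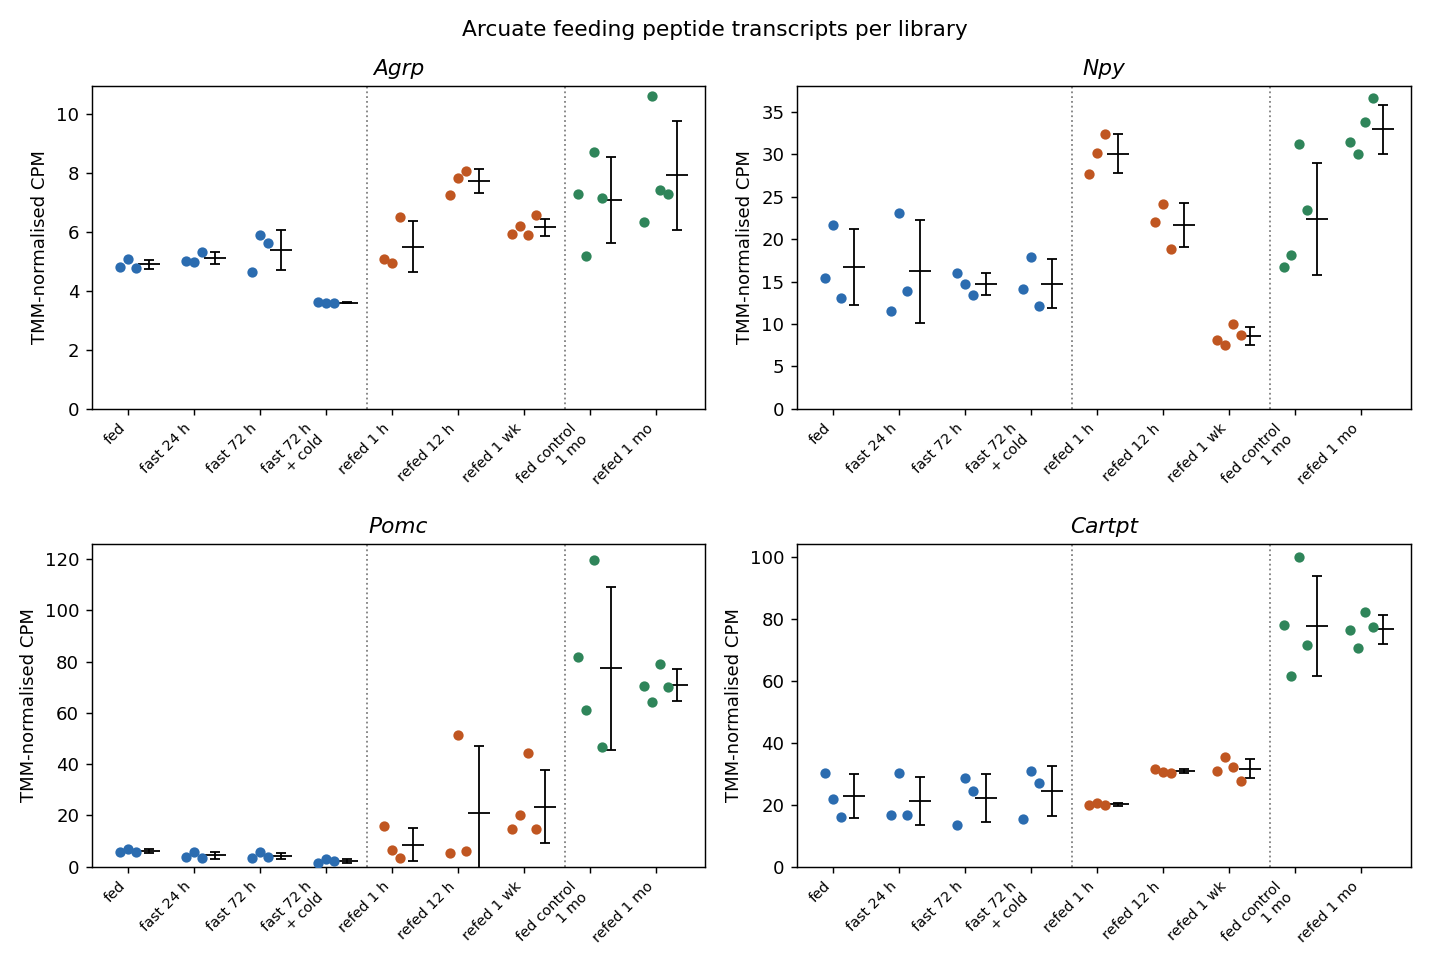
TMM-normalised CPM of Agrp, Npy, Pomc and Cartpt in each library, with a dot per library, bars for mean ± SD per group, and colours and dotted lines that part the 3 count tables. Within the refeeding table Npy stood at 30.1 CPM after 1 h, 21.7 CPM after 12 h and 8.59 CPM after 1 week.

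Libraries from 12 h and 1 week of refeeding were compared to ask what changes as refeeding continues. The labels do not say whether the 1 week libraries were prepared and sequenced with the 12 h ones. Differences of handling and of refeeding time thus cannot be told apart here. Npy fell further, from 21.7 ± 2.64 to 8.59 ± 1.07 CPM (log2 fold change -1.33 ± 0.11, n = 3 and 4, adjusted p = 3.69e-05), and Npy1r fell by 0.48 ± 0.13 (adjusted p = 0.0286). Agrp (-0.33 ± 0.11, adjusted p = 0.0696), Cartpt (0.04 ± 0.08) and Pomc (0.16 ± 0.93) were not called. Genes of sterol synthesis rose. Hmgcs1 (34.6% overlapped) and Msmo1 rose by 0.64 ± 0.09 and 0.57 ± 0.09 on the log2 scale. Of 24 genes of the pathway 13 were higher, 17 when adjusted over the list alone (median 0.38, camera adjusted p = 1.93e-11, adjusted p = 0.360 with an estimated correlation, fry adjusted p = 0.0108). Scd1, a fatty acid desaturase gene, rose from 184 ± 7.70 to 269 ± 18.7 CPM (0.55 ± 0.08). Of 16 fatty acid synthesis genes 6 were higher by either adjustment (median 0.15, adjusted p = 0.360 with an estimated correlation). Atp5e, a subunit of the mitochondrial ATP synthase (ENSMUSG00000016252, chromosome 2, 174461072 to 174464105), went from 15 ± 2.33 to 31.6 ± 3.53 CPM (1.08 ± 0.11, adjusted p = 0.000160). Of 32 nuclear oxidative phosphorylation genes 22 were higher, 27 when adjusted over the list alone (median 0.33, camera adjusted p = 1.71e-18, adjusted p = 0.360 with an estimated correlation). Over all genes the fold change fell with gene span (Spearman rho -0.19). The 7SL RNA genes Rn7s1 and Rn7s2 (49% overlapped each), small non-coding RNAs of the signal recognition particle, were higher at 1 week as well, at 39.7 ± 5.93 and 159 ± 28.1 CPM (2.01 ± 0.20, adjusted p = 0.000854) and at 40.1 ± 7.0 and 207 ± 74.9 CPM (2.37 ± 0.35, adjusted p = 0.00842), and total counts were between 26.1 and 34.1 M per library at 12 h and between 46.9 and 64.3 M at 1 week.

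Astrocyte genes were higher after 1 week, with Fgfr3 at 0.51 ± 0.07, S100b (23.7% overlapped) at 0.58 ± 0.09 and the GABA transporter gene Slc6a11 at 0.42 ± 0.08. Of 13 astrocyte markers 8 were higher, 10 when adjusted over the list alone (median 0.34, camera adjusted p = 8.49e-07, adjusted p = 0.360 with an estimated correlation). The glycolytic gene Pgk1 (0.63 ± 0.08) and 15 of 37 ribosomal protein genes, 24 when adjusted over the list alone (median 0.24, adjusted p = 0.605 with an estimated correlation), were higher. Mt1 rose from 52.3 ± 3.6 to 99.0 ± 7.14 CPM (0.92 ± 0.08, adjusted p = 3.69e-05). The chaperone gene Hspb1 fell by 1.20 ± 0.18 and the immediate early gene Nr4a3 by 0.78 ± 0.16. Of 30 immediate early genes 8 were lower, 14 when adjusted over the list alone (median -0.45, camera adjusted p = 4.25e-07, adjusted p = 0.360 with an estimated correlation). Striatal markers passed camera as lower with none of 12 called (median -0.81, camera adjusted p = 0.000789, adjusted p = 0.606 with an estimated correlation), and their sums were 1413, 1181 and 1503 CPM at 12 h and 750, 470, 1261 and 1010 CPM at 1 week. Endothelial genes Cdh5 (-0.76 ± 0.16) and Eng (-0.89 ± 0.19) were lower. Of 14 endothelial markers 5 were lower and 1 higher, 6 and 1 when adjusted over the list alone (median -0.22, adjusted p = 0.762 with an estimated correlation). Blood transcripts rose, with Hbb-bs from 25.1 ± 4.62 to 195 ± 116 CPM (2.96 ± 0.48, adjusted p = 0.0113). Of 10 blood markers 6 were higher by either adjustment (median 1.76, adjusted p = 0.360 with an estimated correlation). Summed blood markers were 191, 167 and 227 CPM at 12 h and 1369, 503, 533 and 652 CPM at 1 week. Summed meningeal markers were 107, 113 and 129 CPM at 12 h and 159, 160, 203 and 165 CPM at 1 week. In all, 2304 genes were called, 1307 higher and 997 lower. The count became 1122 without 12 h library 2, 589 without 12 h library 3, 1151 without 1 week library 1 and 1296 without 1 week library 2. Of 45 called genes chosen for the text 29 kept their calls without any single library. Calls were lost by 5, 7 and 16 genes without 12 h libraries 1, 2 and 3 and by 4, 3, 3 and 4 without 1 week libraries 1 to 4, among them Hbb-bs, Cdh5, Eng and Npy1r. Adding 1 surrogate variable left 727 called genes, and 13 of the 45 lost their calls, these 4 among them, and voom with quality weights called 3897.

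The genes called between fed and 72 h fasted libraries were followed into the refeeding libraries to ask whether they moved back. Whether they did so between 1 h and 12 h depended on how they were chosen. The 1485 genes higher after the fast had a median log2 fold change of -0.03 (1447 tested, 54.0% opposite in sign, fry adjusted p = 0.569), and the 1587 genes lower after it had 0.02 (1518 tested, 52.8% opposite, fry adjusted p = 0.661). From 12 h to 1 week the medians were -0.07 (60.3% opposite, fry adjusted p = 0.569) and 0.04 (55.3% opposite, fry adjusted p = 0.569). Between the 1-month refed and control libraries they were -0.10 (67.2% opposite, fry adjusted p = 0.405) and 0.06 (60.8% opposite, fry adjusted p = 0.286). The median from 1 h to 12 h of the genes higher after the fast became 0.03 without 12 h library 1, and that of the genes lower after it became -0.06 without 12 h library 1. With the set taken without fed library 2, 197 genes higher after the fast had a median of -0.24 from 1 h to 12 h (70.1% opposite, 59 called opposite and 1 called the same way, fry adjusted p = 0.0289, between 2.83e-06 and 0.911 over all alternatives, camera p = 0.122 with an estimated correlation).

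Of 442 genes called in both comparisons, 185 were higher after the fast and fell from 1 h to 12 h, where 105 would be paired by chance, and 121 were lower after it and rose, where 109 would be. Another 87 were higher in both, against 104 by chance, and 49 lower in both, against 111. The 5 genes called higher at 24 h of fasting, Fkbp5, Arrdc2, Pla2g3, Itgad and Cdkn1a, were all called lower from 1 h to 12 h (median -1.49, fry adjusted p = 2.83e-06). Over 19516 genes the fold changes of the fast and of early refeeding were not correlated in size (r = 0.00, rho = 0.07, across genes, which are not independent replicates).

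Mice refed for 1 month were compared with their own fed controls to ask what remains of the fast. The main difference was in genes of the meninges, the membranes around the brain. Fmod, a collagen-binding proteoglycan gene (ENSMUSG00000041559, chromosome 1, 134037254 to 134048277), stood at 6.26 ± 6.37 CPM in controls and 73.7 ± 20 CPM in refed libraries (log2 fold change 3.53 ± 0.59, n = 4 each, adjusted p = 0.0168). Col1a1, a fibrillar collagen gene, went from 21.4 ± 3.85 to 83.4 ± 23.6 CPM (1.97 ± 0.20, adjusted p = 0.000368), and Foxc1, a transcription factor of meningeal fibroblasts, from 7.38 ± 1.88 to 23.7 ± 4.78 CPM (1.68 ± 0.18, adjusted p = 5.04e-05). Of 14 meningeal markers 13 were higher, 14 when adjusted over the list alone (median 2.81, camera adjusted p = 1.19e-23, adjusted p = 0.339 with an estimated correlation, fry adjusted p = 0.00745). Their sum was 148, 113, 134 and 303 CPM in control libraries 2 to 5 and 977, 1397, 839 and 842 CPM in refed libraries 1, 2, 4 and 5. Endothelial genes were higher, with Cdh5 at 1.09 ± 0.14 (adjusted p = 0.000117) and Kdr at 0.71 ± 0.11. Of 14 endothelial markers 8 were higher, 9 when adjusted over the list alone (median 0.38, camera adjusted p = 5.31e-06, adjusted p = 0.516 with an estimated correlation).

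Immune, glial and neuronal genes also differed at 1 month. Of 19 interferon-stimulated genes 9 were higher, 17 when adjusted over the list alone (median 0.96, camera adjusted p = 1.02e-08, adjusted p = 0.537 with an estimated correlation), with Ifitm3 at 1.40 ± 0.21 and Gbp2 at 1.53 ± 0.23. Of 17 reactive astrocyte genes 12 were higher, 13 when adjusted over the list alone (median 0.81, adjusted p = 0.339 with an estimated correlation), with the complement gene C4b from 123 ± 11.5 to 217 ± 42.7 CPM (0.81 ± 0.13, adjusted p = 0.00171) and the intermediate filament gene Vim at 1.32 ± 0.19. Myelin genes were higher, with Aspa at 0.84 ± 0.16 and Cldn11 at 0.70 ± 0.14. Of 17 myelin markers 5 were higher, 10 when adjusted over the list alone (median 0.44, adjusted p = 0.537 with an estimated correlation). Nefm, a neurofilament gene, fell from 109 ± 10.7 to 81.5 ± 3.69 CPM (-0.42 ± 0.08, adjusted p = 0.00280). Of 13 neuron markers 2 were lower, 4 when adjusted over the list alone (median -0.21, adjusted p = 0.537 with an estimated correlation). Cpt2, of mitochondrial fatty acid import, rose by 0.72 ± 0.13.

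Feeding genes at 1 month included Lepr, the leptin receptor gene (ENSMUSG00000057722, chromosome 4, 101717404 to 101815352), which was higher at 27.8 ± 2.68 against 18.4 ± 2.82 CPM (log2 fold change 0.60 ± 0.12, n = 4 each, adjusted p = 0.00369). Npy was higher at 33.0 ± 2.89 against 22.4 ± 6.59 CPM (0.56 ± 0.16, adjusted p = 0.0401). Gal, the galanin gene (ENSMUSG00000024907, chromosome 19, 3409915 to 3414544), was lower at 28.9 ± 1.11 against 39.4 ± 3.28 CPM (-0.45 ± 0.09, adjusted p = 0.00416). Agrp (0.17 ± 0.19), Pomc (-0.12 ± 0.28) and Cartpt (-0.02 ± 0.12) were not called. Lepr was highest, at 31.7 CPM, in refed library 2, which also held the highest meningeal sum. Among controls Lepr was highest in library 4, at 22.1 CPM, while library 5 held the highest meningeal sum. Of 1506 called genes 947 were higher and 559 lower. The count became 918 without control library 2, 829 without control library 3, 2856 without control library 5, 775 without refed library 2 and 938 without refed library 4. Of 41 called genes chosen for the text 28 kept their calls without any single library, among them Lepr, Gal, Col1a1, Foxc1, Cdh5, Ifitm3 and C4b. Npy and Fmod were among the genes that lost theirs, at 10, 9, 4 and 1 genes without control libraries 2 to 5 and 8, 11, 6 and 5 without refed libraries 1, 2, 4 and 5. Only 130 genes were called with 1 surrogate variable, and 33 of the 41 lost their calls, among them Lepr, Gal, Col1a1, Ifitm3 and C4b but not Foxc1 or Cdh5. With a replicate block, which leaves fewer degrees of freedom, 402 were called and 22 of the 41 lost theirs, Lepr and Gal among them.

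**Figure D4:**
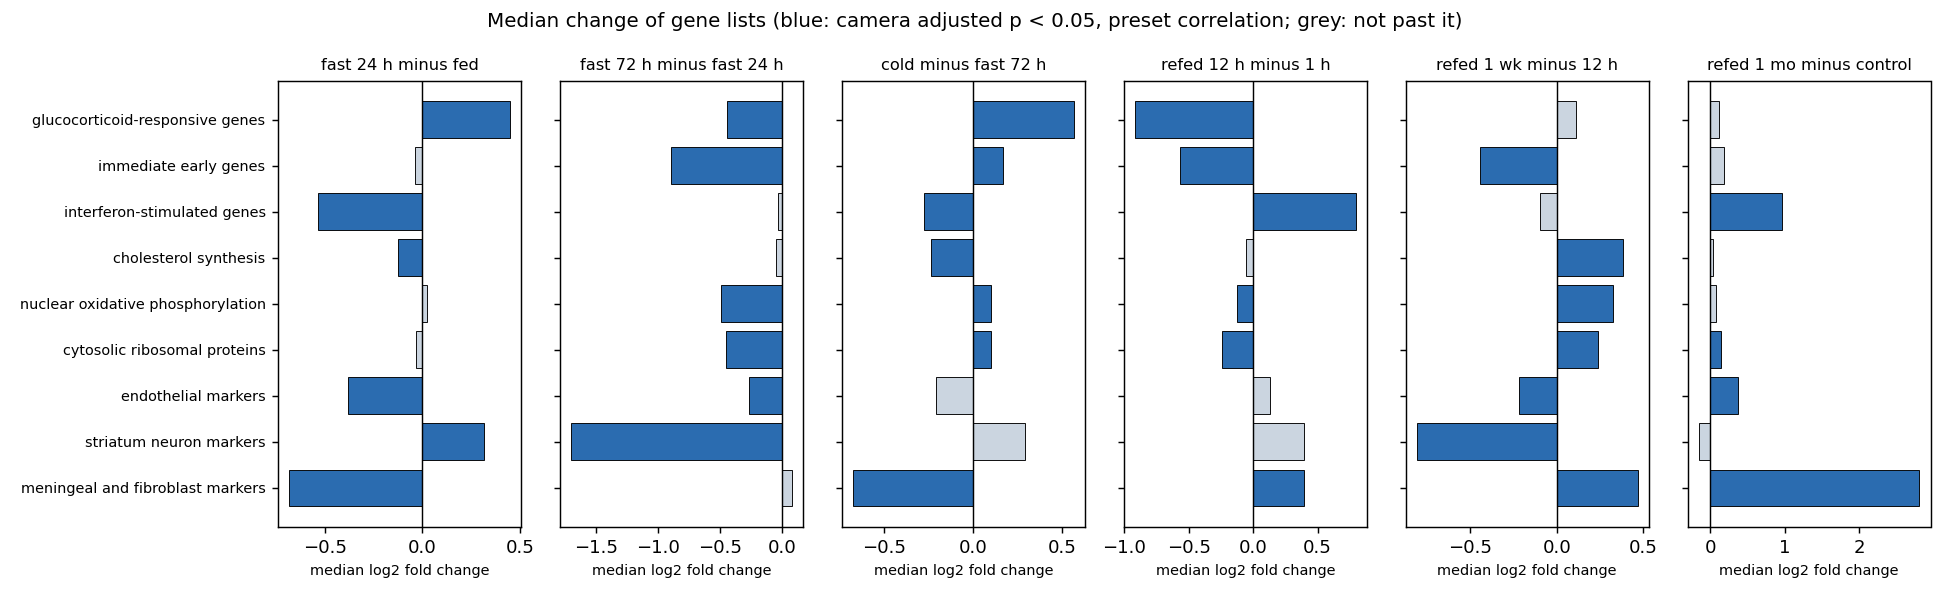
Bars of the median log2 fold change of 9 gene lists in 6 comparisons, with blue bars for lists past a camera adjusted p of 0.05 at the preset correlation. The glucocorticoid-responsive list stood at 0.45 after 24 h of fasting and at -0.92 from 1 h to 12 h of refeeding, and the meningeal list at 2.81 at 1 month.

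Comparisons across count tables asked how refeeding started and whether 1 week restored the fed level, and in these the table and the group cannot be told apart. From the 72 h fast to 1 h of refeeding, Npy was 1.97-fold higher (log2 fold change 0.98 ± 0.21, n = 3 each, adjusted p = 0.00108), Vgf 2.07-fold (1.05 ± 0.12) and Mchr1 2.13-fold (1.09 ± 0.20), while Agrp (-0.02 ± 0.13), Pomc (0.95 ± 0.76) and Cartpt (-0.20 ± 0.28) were not called. Immediate early genes were higher in 25 of 30 cases, 26 when adjusted over the list alone (median 1.15, camera adjusted p = 2.81e-16, adjusted p = 0.282 with an estimated correlation), with Egr4 at 4.55 ± 0.50. Striatal markers were higher in 11 of 12 (median 1.80) and thalamic markers lower in 10 of 12, 12 when adjusted over the list alone (median -1.41), each with an adjusted p of 0.763 with an estimated correlation. Neuroendocrine hormone genes passed camera as higher with 7 of 15 higher and 1 lower by either adjustment, a median of 0.45 and a mean of 0.01 (adjusted p = 0.763 with an estimated correlation). The pituitary hormone genes Gh and Prl stood at 0.0184 ± 0.0318 and 0.101 ± 0.175 CPM in the 72 h libraries and at 16.1 ± 18.2 and 11.3 ± 10 CPM after 1 h. Of 7236 called genes 44.5% were higher, and 53.2% of 7086 with RLE size factors. Of 12 called genes chosen for the text the 3 that lost their calls without a single library were Gh, Prl and Adora2a, with 2, 3 and 3 lost without 72 h libraries 1 to 3 and 3 and 1 without 1 h libraries 1 and 2.

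Between fed libraries and 1 week of refeeding 8943 genes were called, 4145 higher and 4798 lower. Npy was lower after 1 week, at 8.57 ± 1.02 against 17.0 ± 4.54 CPM (log2 fold change -0.98 ± 0.19, n = 4 and 3, adjusted p = 0.000416), and Cck, the cholecystokinin gene, was 5.30-fold lower (-2.41 ± 0.39). Agrp (59.9% overlapped) was 1.23-fold higher (0.30 ± 0.12, adjusted p = 0.0412) and Pomc 3.75-fold higher (1.91 ± 0.71, adjusted p = 0.0408). Oxt, the oxytocin gene, was 2.78-fold higher (1.47 ± 0.43, adjusted p = 0.0115), and Cartpt was not called (0.46 ± 0.26). Glucocorticoid-responsive genes were lower in 17 of 25, 18 when adjusted over the list alone (median -0.72, camera adjusted p = 2.61e-05, adjusted p = 0.739 with an estimated correlation), and endothelial markers in 13 of 14, all 14 when adjusted over the list alone (median -1.34, adjusted p = 0.636 with an estimated correlation). Pomc, Agrp and Oxt lost their calls without single libraries, at 3, 2 and 2 calls without fed libraries 1 to 3 and 1 without each of the 1 week libraries. Summed pituitary markers were 144, 153 and 119 CPM in fed and 157, 184, 303 and 156 CPM in 1 week libraries. Whether pituitary tissue took part in the Pomc difference was not tested. There were 5111 called genes with 1 surrogate variable, and Npy, Pomc and Agrp lost their calls. The fed libraries and the fed 1-month controls, which both came from fed mice, differed in 12305 of 16892 genes tested. In that comparison no list passed camera, which compares a list with all other genes, while 28 of 43 lists passed fry. Pomc differed 11.4-fold there (3.52 ± 0.30, adjusted p = 4.69e-09), at 6.66 ± 0.788 against 76.5 ± 31.5 CPM, and Cartpt 3.11-fold (1.64 ± 0.30), while Agrp (0.39 ± 0.18) and Npy (0.28 ± 0.23) were not called. Tubb3, a neuronal tubulin gene that lies wholly within the span of other genes, was counted at 0 in every fed library and at 404 ± 25.8 CPM in the controls.

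Lists that passed camera in none of the 10 comparisons of the main fit were those of orexigenic peptides, anorexigenic peptides, feeding receptors, leptin and STAT3 targets, local thyroid hormone action, lateral hypothalamus markers, pituitary markers and proliferating cell genes. With the replicate block the lateral hypothalamus markers passed as higher from 12 h to 1 week (camera adjusted p = 0.0373). The authors' own tables of differential expression were available for 7 comparisons, and the fold changes there and here correlated over genes between 0.988 and 1.000. At the authors' q below 0.05 there were 169 genes for 24 h of fasting, 2713 from 24 h to 72 h, 303 for cold, 3260 from 1 h to 12 h, 2915 from 12 h to 1 week, 8130 for fed against 1 week and 2916 at 1 month. Genes past both thresholds numbered 6, 277, 0, 2198, 1782, 6420 and 1506 in that order, all with the same sign in both. What each of the authors' tables divides by what is not stated, and the signs of those for 24 h of fasting, 1 h to 12 h, fed against 1 week and 1 month were turned so that their fold changes and those here correlated positively, so the overall direction there was set by the comparison itself. The authors' tables come from a likelihood ratio test, and their table of fed against 1 week holds 3 of the 4 one-week libraries.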

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

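Tests in this part chosen only after the result was seen are those on liver and muscle, on striatal and immediate early, and on meningeal transcripts. Single libraries far from the others of their group were looked for in groups of 4. The gap of the highest or lowest library to its nearest neighbour was divided by the group's range and held against Dixon's 95% critical value. This singled out 15 of 169 groups of values. Chance gives about 1 in 20 for independent values, which genes read from the same libraries are not. In the refeeding libraries 9 of 25 liver genes, 10 of 18 skeletal muscle genes, 12 of 12 striatal genes and 12 of 14 meningeal genes of the lists used below were expressed enough to be tested.

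Control library 5 of the 1-month table stood apart for some meningeal genes. Its Fmod level was 15.8 CPM, against 2.88 to 3.48 CPM in the other controls (gap over range 0.953), and the ratio was 0.938 for Igfbp6, 0.966 for Slc22a6, 0.891 for Slc13a4, 0.835 for Osr1 and 0.901 for Cdh1. The meningeal list sum of that library, 303 CPM against 113 to 148 CPM in the other controls, was not singled out. Refed 1-month library 2 stood apart with higher Islr (0.955, 97.2 against 57.1 to 58.9 CPM) and Srgn (0.911), with lower Lhx9 (0.948, 1.29 against 1.58 to 1.60 CPM), and with a liver transcript sum of 124 CPM against 11.5 to 13.7 CPM (0.980). Nefm was lowest in refed 1-month library 1, at 75.9 CPM against 83.1 to 83.6 CPM (0.930). At 1 week of refeeding, library 1 had the highest Hbb-bs (0.841, 367 against 123 to 162 CPM) and Hbb-bt (0.903) and the lowest Npy1r (0.840, 10.7 against 14.6 to 15.4 CPM). The meningeal sum was highest in 1 week library 3, at 203 CPM against 159 to 165 CPM (0.864).

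Liver and muscle transcripts were lower after the 72 h fast than in fed libraries. A change with fasting shared by all fed hypothalami is argued against, since the muscle sum of the lowest fed library was 0.884 times that of the highest 72 h library (1.00 for the liver sum). Liver and muscle RNA mixed into single fed libraries may account for the fall, as the highest fed library held 143.3 times the liver sum of the lowest and 161 times the muscle sum. Liver transcripts were not confined to fed libraries, as the 24 h libraries held 72.0, 239 and 91.2 CPM of them, against at most 9.42 CPM in the 72 h libraries. How such RNA entered the libraries, by dissection or in later handling, was not tested.

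Striatal and immediate early genes fell together from 24 h to 72 h of fasting. Less striatal tissue and lower expression of the striatal genes cannot be told apart, since the lowest 24 h sum, 1.91 times the highest 72 h sum, would separate the groups under both, and libraries within another single group differed by up to 2.69 times. If there was less striatal tissue, it could also carry the immediate early genes. In 10 refeeding libraries the deviations of both lists from their group means went together (Spearman rho 0.879, permutation p = 0.00664, Pearson r 0.898, permutation p = 0.00665, 100000 two-sided resamples within groups, r = 0.803 without the 2 libraries farthest from the median). A fall of neuronal activity with a longer fast stays open as well, as untested.

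Meningeal genes were higher at 1 month after refeeding than in controls. A lower share of neurons that raises every other cell type alike is argued against, since the meningeal median exceeded the highest of 4 other cell type lists by 2.37 on the log2 scale. More meningeal tissue in the refed libraries and a lasting change of the meninges after a fast cannot be told apart and both stay open, since the lowest refed sum, 2.77 times the highest control sum, would separate the groups under both. Sums within the controls differed by up to 2.68 times and within the refed libraries by up to 1.67 times. Whether more meningeal tissue also carried the rises of Lepr and of endothelial, interferon-stimulated and reactive astrocyte genes was not tested.

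Counts of called genes were set against all other splits of the same libraries into groups of the same sizes. For 3 against 3 libraries there are 10 splits, which are too few for a share under 0.05. The real split and the highest other gave 333 and 0 genes from 24 h to 72 h, 3072 and 0 for fed against 72 h, 0 and 5 for cold, 2834 and 0 from 1 h to 12 h, and 7236 and 0 from 72 h to 1 h of refeeding. For fed against 24 h the real split gave 7 genes, 2 of the 10 splits gave at least as many, and the highest other gave 4837. That split joined fed libraries 1 and 2 with 24 h library 2, the 3 libraries richest in reads of mitochondrial-like pseudogenes, and so points to a structure of the samples apart from feeding. With 35 splits the real split gave the most genes from 12 h to 1 week (2304 genes, highest other 322) and at 1 month (1506, highest other 1). It also did for fed against 1 week (8943, highest other 4952) and for fed against the 1-month controls (12305, highest other 8419). Each count was reached by 1 of the 35 splits, the smallest share that 35 splits can give, so chance was not excluded. In the last 2 comparisons the table and the group cannot be told apart, so the rank tells nothing of feeding. For cold all 10 splits reached the real count of 0.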

How the results depend on the processing

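Tests in this part chosen only after the results were seen are those without mitochondrial-like pseudogenes, those without the 3 libraries richest in their reads, those with the trend of gene span removed, and those with the fasting genes taken without fed library 2. Of 302 values of named genes, direction and call were the same for 300 with RLE size factors, for 280 of 299 with DESeq2 and for 295 of 297 with a filter at a mean CPM of 1. They were the same for 158 with 1 surrogate variable, where 129 lost their call, and for 84 of 131 without the 3 libraries, where 41 lost it. Leaving out each library gave 1967 values, of which 1555 were the same, 372 lost the call, 4 gained it and 36 changed sign. Where no reason is given below, the cause was not tested.

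With DESeq2 the counts of called genes were 240 for fed against 24 h, 1776 from 24 h to 72 h, 4707 for fed against 72 h and 57 for cold. With voom and quality weights they were 3952, 2909, 7554 and 28 in that order, and 3897 from 12 h to 1 week. With 1 surrogate variable they were 23 for fed against 24 h, 0 from 24 h to 72 h, 2 for fed against 72 h, 727 from 12 h to 1 week, 130 at 1 month and 5111 for fed against 1 week. No filter gave 13 and a filter at a mean CPM of 1 gave 12 for fed against 24 h. Without the 3 libraries rich in mitochondrial-like reads there were 52 for fed against 24 h, 688 from 24 h to 72 h and 481 for fed against 72 h, with fewer samples. Removing the span trend gave 13 for fed against 24 h, 815 from 24 h to 72 h and 1 for cold. The replicate block moved 1 count by more than 1.5 times, to 402 at 1 month, where the block leaves fewer degrees of freedom. Under it 31 of 268 named genes lost their call, over all the comparisons it was run on.

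Leaving out each library in turn gave between 3 and 56 genes for fed against 24 h, 0 and 328 from 24 h to 72 h, 434 and 5446 for fed against 72 h, and 0 and 5 for cold. It gave between 1314 and 3537 from 1 h to 12 h, 589 and 3050 from 12 h to 1 week, and 775 and 2856 at 1 month. It left the counts across tables within 1.5 times, at 5485 to 6116 from 72 h to 1 h of refeeding, 7305 to 9393 for fed against 1 week and 11884 to 12029 for fed against the 1-month controls. Camera with an estimated correlation kept 1 of 126 list calls, and fry passed 57 of them.

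The fasting genes changed direction with the way they were chosen. The sets called after 24 h held 5 higher and 2 lower genes, so their medians rest on few genes. From 1 h to 12 h, the genes higher after 72 h had a median of 0.011 with sets from DESeq2 calls and 0.012 with changes of at least 0.5 on the log2 scale. It was -0.24 with the set taken without fed library 2, and the genes higher after 24 h had -1.49. The last 2 sets passed fry, with camera p of 0.122 and 0.00185 at an estimated correlation. The genes lower after 72 h had -0.0036 with DESeq2 calls, and those lower after 24 h had -0.15. From 12 h to 1 week the genes lower after 72 h had -0.020 with changes of at least 0.5 and -0.14 with the set without fed library 2. Those lower after 24 h had -0.40. At 1 month the genes higher after 24 h had 0.083. Leaving out each library moved the medians between -0.067 and 0.026 and between -0.055 and 0.055 from 1 h to 12 h, for genes higher and lower after 72 h, and between -0.00034 and 0.098 for the lower ones from 12 h to 1 week.

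Signs changed for feeding peptides that were not called. With 1 surrogate variable Npy had 0.087 for fed against 24 h, 0.65 from 24 h to 72 h and 0.73 for fed against 72 h, Pomc 0.48 from 24 h to 72 h, 0.073 for fed against 72 h and 0.0085 at 1 month, and Cartpt 0.44 for fed against 72 h and -0.048 from 12 h to 1 week. Without the 3 libraries Npy had 0.20 from 24 h to 72 h and 0.16 for fed against 72 h, Pomc 0.22 from 24 h to 72 h, and Cartpt 0.054 for fed against 24 h and 0.46 for fed against 72 h. With the span trend removed Agrp had -0.019 from 24 h to 72 h and 0.12 from 72 h to 1 h of refeeding, Pomc 0.087 from 24 h to 72 h, Cartpt 0.14 for fed against 72 h and -0.016 from 12 h to 1 week, and Npy -0.075 for fed against the 1-month controls. With voom Npy had 0.12 and Pomc 0.23 from 24 h to 72 h, and Cartpt -0.024 for cold. The replicate block gave Npy -0.025 for cold. From 72 h to 1 h of refeeding Agrp had 0.037 with DESeq2, 0.033 with RLE, 0.0076 with a filter at a mean CPM of 1, 0.045 with these groups alone and 0.043 without mitochondrial-like pseudogenes.

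Called genes changed sign in fed against 72 h with 1 surrogate variable, at 0.63 for Myh4, 1.58 for Tnnt3, 0.32 for Tnni2 and -0.12 for Meg3, and none was then called. Leaving out single libraries moved uncalled peptides across 0. For fed against 24 h the ranges were -0.39 to 0.19 for Npy and -0.45 to 0.16 for Cartpt. From 24 h to 72 h they were -0.00065 to 0.16 for Agrp, -0.34 to 0.20 for Npy, -0.30 to 0.22 for Pomc and -0.16 to 0.41 for Cartpt. For fed against 72 h they were -0.34 to 0.046 for Npy and -0.27 to 0.22 for Cartpt, and for cold -0.16 to 0.13 for Npy and -0.086 to 0.42 for Cartpt. Pomc ranged from -0.57 to 2.10 from 1 h to 12 h, where 12 h library 2 alone held its high level, and from -0.36 to 2.03 from 12 h to 1 week, where Cartpt ranged from -0.013 to 0.094. At 1 month Agrp ranged from -0.013 to 0.28, Pomc from -0.30 to 0.16 and Cartpt from -0.12 to 0.12. From 72 h to 1 h of refeeding Agrp ranged from -0.12 to 0.079 and Cartpt from -0.42 to 0.056. The 1-month libraries had the fewest counts and the highest recovery of simulated 1.5-fold changes, 73%. The simulated changes were in genes above a minimum mean count, so this does not show whether depth set the number of calls.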

Other observations

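Sspn and Il31ra, which are not among the gene lists, were chosen after their values were seen. Sspn encodes sarcospan, a membrane protein of the dystrophin complex, and Il31ra a subunit of the receptor for the cytokine IL-31. In the fasting table Sspn stood at 527 ± 84.5 CPM in fed libraries (SD, n = 3), 282 ± 24.4 CPM after 24 h (n = 3) and 146 ± 94.8 CPM after 72 h (n = 3), and Il31ra at 53.0 ± 6.23, 35.1 ± 3.10 and 22.1 ± 15.5 CPM in the same groups. In the refeeding table Sspn stood at 33.7 ± 27.1 CPM after 1 h, 11.5 ± 1.98 CPM after 12 h and 14 ± 3.41 CPM after 1 week. In the 1-month table it stood at 3.93 ± 0.899 CPM in controls and 3.99 ± 0.782 CPM in refed libraries (n = 4 each). Il31ra stood at 3.04 ± 2.09, 1.84 ± 0.119 and 1.70 ± 0.308 CPM after 1 h, 12 h and 1 week of refeeding. In the 1-month table Il31ra stood at 0.513 ± 0.441 CPM in controls and 2.90 ± 0.643 CPM in refed libraries. For Sspn the fed libraries of the fasting and the 1-month table thus differed far more than any groups within a table, and the cause was not tested.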
